A study of Mus musculus with 16 samples.

How the data were processed

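Total RNA of primary mouse pancreatic exocrine cells, infected with Ad-mCherry, with Ad-PDX1, with Ad-DN-REST or with the last 2 together, was measured by bulk MARS-seq at day 5. Per the labels' protocols, clusters of exocrine cells were infected overnight at titers of 40 (Ad-mCherry), 10 (Ad-PDX1) and 30 (Ad-DN-REST) infectious units per nl, washed, plated on collagen and sequenced on a NextSeq 500. The labels used here do not say whether cells given a single virus also received control virus to equalise the titer. Samples were grouped by the virus named in their titles, 4 biological replicates per group, and the replicate letters are not stated to mark shared isolations.

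The main file holds raw UMI counts per gene and library, which the authors made before deposit and did not normalize, as their whole-number values and unequal totals show. Per the submitters' processing notes, bcl2fastq, cutadapt 1.8.3, STAR, HTSeq and DESeq2 were used with mm10; the roles of these tools, their other versions and the gene annotation are not given in the sources used here. A further table of the authors' deposited results lists 2485 genes in 6 comparisons with the authors' log2 fold changes, the authors' adjusted p-values, and the authors' baseMean, a signal that is the mean normalized count. Only its counts of genes and their directions are used, each named as the authors'. The deposited UMI table names 12851 genes, with a maximum of at least 6 UMIs in some library for each; 0 of its lines name no gene and 0 of its columns lack a matching sample. Genes that are not in it were not analysed here. UMIs are counted once per molecule, so intervals and floors given here cover counting error of molecules. Reads shared between near-identical genes (trypsinogens, elastases, Reg, Sprr and Lce genes) could be split between them by the counting, so these genes are uncertain as individuals.

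From the counts, log2 fold changes, standard errors and p-values were computed with edgeR 4.0.16 in R 4.3.3: filterByExpr over the 4 groups (minimum count 10, minimum total 15), TMM scaling, a quasi-likelihood fit (glmQLFit) with 1 coefficient per group over all 16 libraries, and glmQLFTest with Benjamini-Hochberg adjustment, a gene passing at an adjusted p under 0.05. The filter removed 2626 genes and kept 10225, which hold 99.7% of the UMIs. The fit had 12 residual degrees of freedom and a common biological coefficient of variation of 0.155. TMM factors lay between 0.945 and 1.03. All p-values are two-sided. The 5 comparisons of pairs of groups and the interaction used this fit; a gene counted as beyond both single viruses where the combination passed against each in the same direction. CPM are counts scaled to the TMM-adjusted library size, given as mean ± SD. For each gene that the report gives as risen or fallen between 2 groups, all 4 libraries of the higher group had a higher CPM than all 4 of the lower.

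Library totals ran from 1592403 to 4580727 UMIs. Replicates of a group correlated across genes at r = 0.966 to 0.978 on log2 CPM, and a chi-square per degree of freedom of 3.56 to 9.93 between them showed that no pair was the same library deposited again. Where a gene had no UMI in a group, the fold was set against a floor of 3 counts over that group and is a lower bound; with 1 to 3 counts the ratio of CPM is given with an exact binomial (Clopper-Pearson) 95% interval. Positions are those of GENCODE M21 on GRCm38/mm10, matched by symbol for 96.4% of the genes in the table; this annotation may differ from the authors'. All genes given with a position are protein-coding.

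Before the data were examined, the groups, the tests, the alternatives, 21 gene lists and the rule for named genes were fixed. The lists are endocrine hormones, endocrine transcription factors, beta-cell function, neuroendocrine granule and exocytosis genes, RE1 targets of REST, acinar digestive enzymes, acinar transcription factors and receptors, ductal and progenitor markers, injury and Reg genes, interferon response, inflammatory chemokines, unfolded protein and stress response, p53 and apoptosis, cell cycle, fibroblast and stellate markers, macrophage and leukocyte markers, endothelial markers, stomach and intestine genes, liver genes, the Notch pathway and mitochondrially encoded mRNAs. The last had 0 genes in the table and was not tested. Lists were tested with camera (limma 3.58.1; log-CPM with prior count 2, correlation preset at 0.01, adjusted over all lists and comparisons), and with an estimated correlation and with fry beside it. Members were counted past the edgeR test over all genes and adjusted over the list alone.

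The rule for named genes took, in each comparison with Ad-mCherry, the 8 largest rises and the 8 largest falls past the test with a mean of at least 10 UMIs in the higher group and separate libraries, and 5 and 5 in the other comparisons. It added up to 4 members of each list by lowest p, and a fixed set including Pdx1, Rest, Gcg, Iapp, Neurod1, Chga, Snap25, Stmn2, Cpa1, Krt19 and Sox9, in all 226 genes.

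Alternatives were DESeq2 1.42.0, size factors of DESeq2 in edgeR, total UMIs without TMM, no filter, a filter of at least 10 UMIs in 4 libraries, the 2 groups compared alone, the replicate letter as a block, and each library left out in turn; thinning all libraries to the smallest total was added after seeing the data. The correlation and covariance of the single-virus fold changes were set beside 20 simulated sets of unchanged groups. In these sets the controls were simulated too and shared between the comparisons. The overlap of the lists was set beside 6 uses of split controls. Other groupings of the libraries were fitted for each count, all 35 for a pair of groups and 100 drawn at random otherwise. The test was tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold among 10225, per comparison. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.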

Results

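Cells of the mouse exocrine pancreas, the tissue whose acinar cells make digestive enzymes and whose ducts drain them, were studied in primary culture after infection with adenoviruses, which carry a chosen gene into cells. Ad-mCherry carried a red fluorescent protein and served as the control. Ad-PDX1 carried PDX1, a homeodomain transcription factor of pancreas development and of insulin-producing beta cells. Ad-DN-REST carried a dominant-negative form of REST, a repressor that binds the RE1 DNA motif and silences neuronal genes outside the nervous system. Cells received a single virus (the mCherry, PDX1 and DN-REST groups) or the last of these along with Ad-PDX1 (the combination group). Each of the 4 groups held 4 biological replicates lettered A to D, all from C57BL/6 mice. RNA of day 5 after infection was measured by bulk MARS-seq, which tags the 3′ end of each mRNA with a unique molecular identifier (UMI), so that copies made by PCR count as a single molecule. The design asks what PDX1 and the block of REST each do to exocrine cells, and what they do together.

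The 16 libraries held 1592403 to 4580727 UMIs each, with a median of 3026224.5. Control library B was the shallowest and combination library D the deepest, a ratio of 2.88. Group means were 2574060 UMIs (mCherry), 2980930 (PDX1), 3547910 (DN-REST) and 3500170 (combination). The difference in total UMIs between the DN-REST and mCherry groups did not pass an exact two-sided permutation test (p = 0.0857, n = 4 per group). In a single library a count of 3 UMIs corresponds to 0.655 to 1.88 CPM, the usual count scaled to library size, depending on the library. The table listed 12851 genes, of which 10225 had enough UMIs to be tested.

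The acinar enzyme list, written before the data were examined, also holds other acinar secretory genes, among them Spink1, a trypsin inhibitor, Gp2, Cuzd1 and Tff2, the last also in the stomach and intestine list. It took 0.867% ± 0.148 of all UMIs in the mCherry group, 3.55% ± 0.825 in the PDX1 group, 1.99% ± 0.256 in the DN-REST group and 4.76% ± 0.606 in the combination group (SD, n = 4 each). Ribosomal protein genes took 13.4% ± 0.187, 11.8% ± 0.171, 12.7% ± 0.589 and 10.8% ± 0.326 in the same order. Fibroblast markers, dominated by Fn1, took 0.563% ± 0.0303, 0.282% ± 0.0295, 0.766% ± 0.0580 and 0.240% ± 0.0239. Of 48 exact two-sided permutation tests on such library measures, the lowest p was 0.0286, the smallest that 4 against 4 libraries can give, and 0.0762 after Benjamini-Hochberg (BH) adjustment, so none passed. With this floor, a test that did not pass does not show that the shares were alike.

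**Figure D1:**
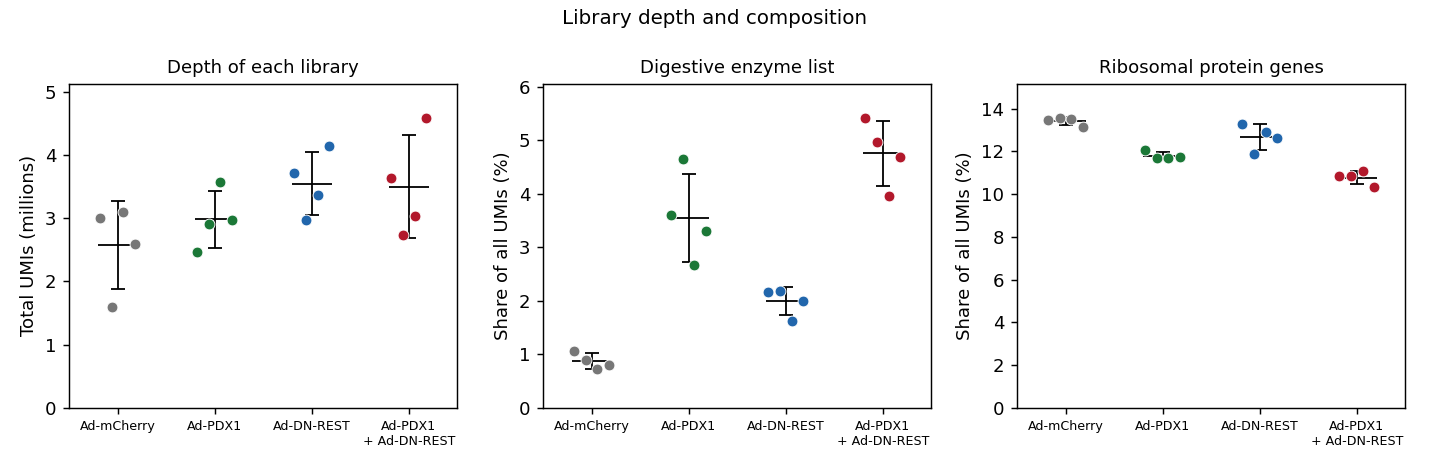
Total UMIs (left), and the share of all UMIs in percent taken by the acinar digestive enzyme list (middle) and by ribosomal protein genes (right), for each of the 16 libraries by group. Dots are libraries and black marks are the mean ± SD (n = 4); the enzyme share averaged 0.867% in the mCherry group and 4.76% in the combination group.

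The gene carried by Ad-PDX1 was read first. Pdx1 (chromosome 5, 147269959 to 147275848, plus strand of GRCm38/mm10) counted 3 to 8 UMIs per mCherry library, 40 to 101 per PDX1 library, 10 to 38 per DN-REST library and 105 to 212 per combination library. Its level was 2.17 ± 0.747, 26.3 ± 11.2, 4.77 ± 2.98 and 48.9 ± 9.56 CPM in that order (SD, n = 4). It rose in the PDX1 group (log2 fold change 3.55, SE 0.38, adjusted p = 1.62e-08, edgeR quasi-likelihood test with BH adjustment). Pdx1 was also higher in the combination than in the PDX1 group (0.91, SE 0.26, adjusted p = 0.0141), which did not pass without PDX1 library D (adjusted p = 0.0661) or combination library A (0.0536). Rest counted 0 to 9 UMIs in any library and was too low to be tested. A 3′ tag reads a virus transcript only if that transcript keeps the mouse 3′ end, which the sources used here do not give, so neither count measures the dose of virus.

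The comparison of the PDX1 group with the mCherry group asks what PDX1 alone does to exocrine cells. Pyy, which encodes peptide YY, a hormone of pancreatic endocrine and gut cells (chromosome 11, 102106676 to 102107832, minus strand), went from 43.0 ± 10.1 to 2531 ± 239 CPM (SD, n = 4; log2 fold change 5.86, SE 0.22, adjusted p = 1.58e-18, edgeR with BH adjustment). The acinar enzyme list rose as a group, with all 27 tested members past the test. Cpa1, carboxypeptidase A1 (chromosome 6, 30639218 to 30645363, plus strand), went from 64.3 ± 12.5 to 873 ± 177 CPM (log2 fold change 3.76, SE 0.16, adjusted p = 2.28e-17). Prss2 and Try4, trypsinogens whose reads can be shared with near-identical genes, rose by 2.96, SE 0.12, and 4.11, SE 0.13, on the log2 scale. The acinar receptor for cholecystokinin, Cckar, rose by 5.79, SE 0.20. Cell cycle genes fell, among them Ube2c, which helps end mitosis, from 157 ± 19.5 to 47.6 ± 7.89 CPM (log2 fold change -1.73, SE 0.15, adjusted p = 9.82e-11). Falls were also seen in Fn1, fibronectin (-2.74, SE 0.11), and in Cdkn2a, an inhibitor of the cell cycle (-4.17, SE 0.24).

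Of the 10225 genes, 3152 passed the test in the PDX1 group (30.8%), 1583 higher and 1569 lower, and 1196 of them differed by at least 2-fold. Total-UMI scaling gave 1527 and 1637, or 48.3% higher in place of 50.2%. In 27.5% of the tested genes all 4 libraries of a group lay above all 4 of the other, against 2.86% by chance. Several strong rises started from a count near 0. Myl1, a muscle myosin light chain, had no UMI in the mCherry group and was at least 61.3-fold higher with PDX1, and Ppapdc1a was at least 21.8-fold higher, both with the group's count of 0 taken as 3. For genes with 1 to 3 control counts the ratio of CPM is given with its 95% exact binomial interval: 207 (56.9 to 1710.4) for Pnoc, prepronociceptin, and 151 (26.7 to 5989) for Kirrel3. This ratio was 102 (27.9 to 847) for Cuzd1, an acinar zymogen granule gene, and 63.2 (17.2 to 527) for Iapp, the islet amyloid peptide that beta cells release with insulin. Afp, alpha-fetoprotein, fell by a ratio of 63.1 (17.1 to 528), and Igf2bp1 by 49.3 (16.5 to 242).

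The acinar enzyme list passed camera, the gene set test used here (median log2 fold change 3.76, adjusted p = 6.33e-34, and 0.00337 with its estimated correlation of 0.275; the count of 27 was the same adjusted over the list alone). Endocrine hormone genes passed it (4 of 7 rose, 5 adjusted over the list alone; adjusted p = 1.52e-04). So did beta-cell function genes (4 of 7 rose; adjusted over the list alone, 4 rose and 1 fell; adjusted p = 0.00470) and neuroendocrine granule genes (7 of 19 rose, the same adjusted over the list alone; adjusted p = 0.0149). The beta-cell members that rose were Papss2, Iapp, Cpe and Pcsk1. Iapp is also in the hormone list, and Cpe and Pcsk1 are also in the granule list, so these sets are not independent in any comparison. Cck, which encodes cholecystokinin, rose by 2.86, SE 0.28, and Papss2 of the beta-cell list by 4.29, SE 0.22. Among injury and Reg genes 11 rose and 4 fell of 19, with 11 and 5 adjusted over the list alone, with Reg3b (4.57, SE 0.18), Reg3g (5.49, SE 0.22) and Reg2 (4.90, SE 0.21) among the rises. These are secreted proteins of the stressed pancreas and close relatives that can share reads. That list's adjusted p was 0.00470, and 0.0510 with an estimated correlation. Among stomach and intestine genes 4 rose and 1 fell of 8, the same adjusted over the list alone. Rises included Tff2, a mucosal peptide (3.05, SE 0.25), and Ctse, cathepsin E (2.08, SE 0.18). The set's adjusted p was 0.0218, and 0.269 with an estimated correlation.

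Cell cycle genes were lower as a set with PDX1: 1 rose and 26 fell of 29, the same adjusted over the list alone (median -1.57, adjusted p = 5.72e-15, and 0.00718 with an estimated correlation), including Ccne1 (-2.41, SE 0.21). Among p53 and apoptosis genes 1 rose and 12 fell of 19, with 2 and 12 adjusted over the list alone. The falls included Mdm2 (-0.80, SE 0.11) and Pmaip1 (-0.95, SE 0.10), both targets of p53. This list's adjusted p was 0.00656, and 0.108 with an estimated correlation. Fibroblast and stellate markers split, as 10 rose and 3 fell of 18, with 13 and 3 adjusted over the list alone, with Fn1 among the falls (median 0.75, adjusted p = 0.0313, 0.445 with an estimated correlation and 0.0651 with fry, a self-contained set test). The remaining lists did not pass camera in this comparison: endocrine transcription factors (adjusted p = 0.173), acinar transcription factors and receptors (0.377), ductal and progenitor markers (0.620), and REST target genes with an RE1 motif (0.390). Nor did those of the interferon response (0.720), chemokines (0.900), unfolded protein response (0.4998), leukocytes (0.126), endothelium (0.368), liver (0.173) and the Notch pathway (0.126). Krt20, an epithelial keratin of the ductal list, fell (-1.47, SE 0.14), and Gata4 of the acinar regulators rose by 1.17, SE 0.16.

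**Figure D2:**
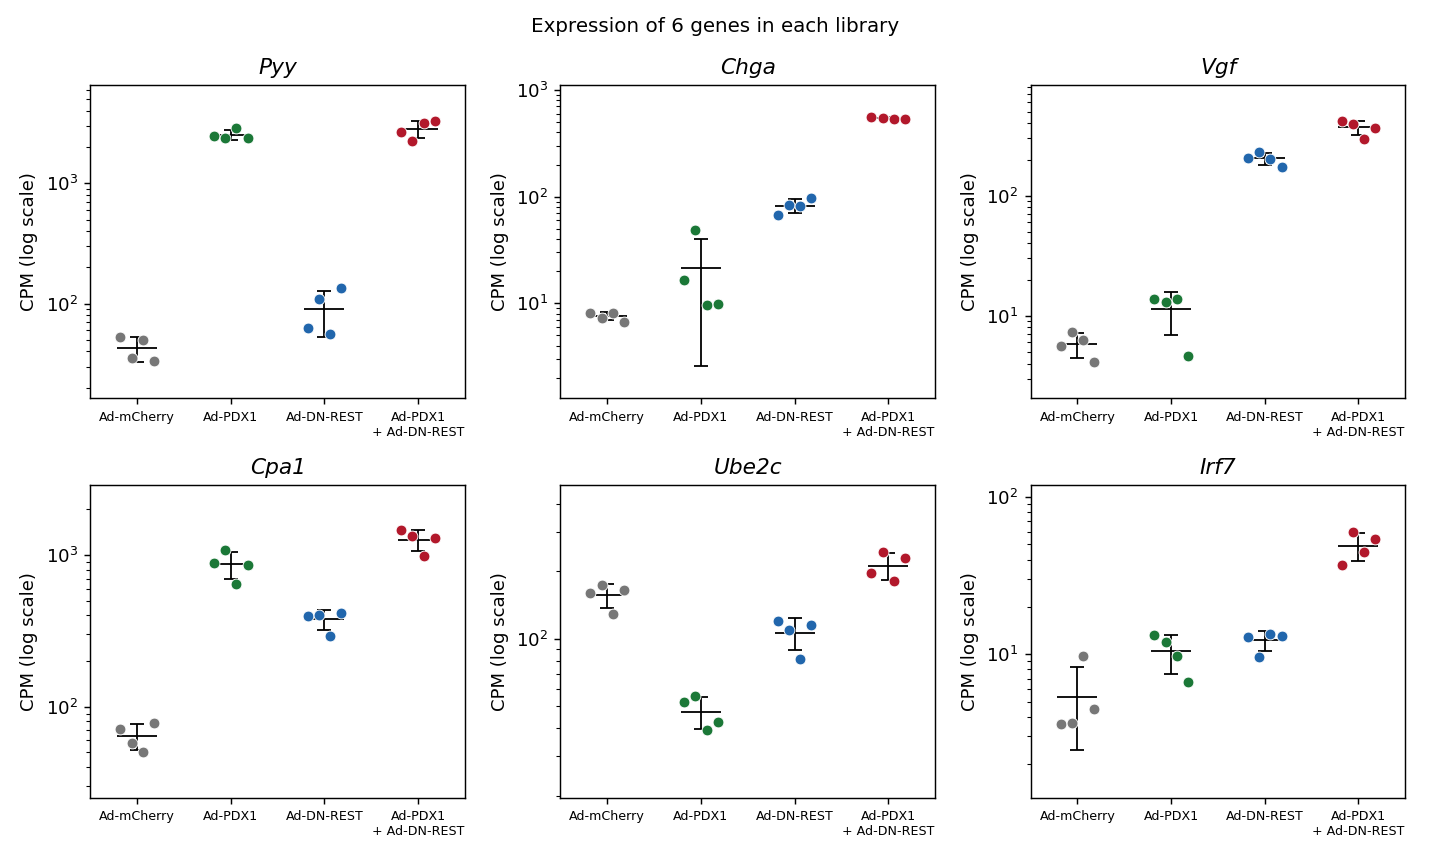
CPM on a log axis of Pyy, Chga, Vgf, Cpa1, Ube2c and Irf7 in each of the 16 libraries by group, scaled by TMM. Dots are libraries and black marks are the mean ± SD (n = 4); Pyy averaged 43.0 CPM in the mCherry group and 2531 in the PDX1 group, and Chga 7.63 and 543 in the mCherry and combination groups.

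The comparison of the DN-REST group with the mCherry group asks what follows from blocking REST alone, with a total titer that may be lower. Genes that REST is known to repress rose: Vgf, a secreted neuroendocrine peptide precursor (chromosome 5, 137026392 to 137033351, plus strand), went from 5.84 ± 1.36 to 205 ± 23.6 CPM (SD, n = 4; log2 fold change 5.15, SE 0.21, adjusted p = 6.91e-17, edgeR with BH adjustment). Chga, chromogranin A of hormone granules (chromosome 12, 102554969 to 102565028, plus strand), went from 7.63 ± 0.684 to 82.3 ± 12.4 CPM (log2 fold change 3.41, SE 0.32, adjusted p = 2.08e-09). Stmn2, a neuronal microtubule regulator, rose by 5.37, SE 0.30, Snap25, a membrane fusion protein of synapses, by 5.06, SE 0.49, and Ap3b2, a neuronal vesicle coat subunit, by 5.91, SE 0.38. Digestive enzymes rose here too, with Cpa1 at 378 ± 55.6 CPM (2.55, SE 0.16) and Prss2 at 3204 ± 318 CPM (2.40, SE 0.12). Cell cycle genes fell, one being Plk1, a mitotic kinase (-1.39, SE 0.22). Among the strongest falls were Ube2ql1 (-3.33, SE 0.45) and Eva1c (-3.06, SE 0.26).

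DN-REST moved 1315 genes past the test (12.9%), 724 higher and 591 lower, of which 509 differed by at least 2-fold. Total-UMI scaling gave 654 higher and 675 lower, or 49.2% higher in place of 55.1%. Of the 34 tested genes written down as RE1 targets, 24 rose and 0 fell, with 27 and 1 adjusted over the list alone (median 2.84, camera adjusted p = 9.23e-28, and 8.06e-06 with an estimated correlation). The median was the same with genes at 0 set at their bound. Xkr7, Lhfpl4 and Bsn, a scaffold protein of synapses, had no UMI in the mCherry group and were at least 13.4-fold, at least 12.4-fold and at least 10.6-fold higher. Asphd1, Gdap1l1 and Stmn3 had a single control UMI each, with CPM ratios of 228 (40.6 to 9031), 151 (26.9 to 6011) and 127 (22.5 to 5043). Neuroendocrine granule and exocytosis genes rose as a set (12 of 19, 13 adjusted over the list alone; median 2.45, adjusted p = 6.28e-12), with Ptprn2 (4.37, SE 0.28) and Ptprn (3.58, SE 0.15), membrane proteins of dense-core granules, among them. Of 7 hormone genes 2 rose, the same adjusted over the list alone, one being Npy, neuropeptide Y (2.52, SE 0.17). That list's adjusted p was 0.0114, and 0.0792 with an estimated correlation.

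Of the acinar enzyme list 22 of 27 members rose with DN-REST, 25 adjusted over the list alone (median 1.63, adjusted p = 2.17e-26, and 0.00718 with an estimated correlation). Cell cycle genes were lower (1 rose and 16 fell of 29, with 1 and 20 adjusted over the list alone; median -0.64, adjusted p = 1.94e-08, and 0.0361 with an estimated correlation). Fibroblast and stellate markers were higher (11 rose and 0 fell of 18, with 11 and 1 adjusted over the list alone; median 0.92), including Vim, vimentin (2.12, SE 0.13), and Tagln, transgelin (1.2999, SE 0.16). This set's adjusted p of 1.25e-07 became 0.0781 with an estimated correlation. Among p53 genes 0 rose and 6 fell of 19, with 1 and 9 adjusted over the list alone, at an adjusted p of 0.00507, and 0.0988 with an estimated correlation. Endocrine transcription factors did not pass as a set (adjusted p = 0.4998; 2 of 9 rose, the same adjusted over the list alone), although Insm1, a zinc finger factor of endocrine differentiation, rose by 2.17, SE 0.38. Camera placed that list above other genes while its median was -0.04. The progenitor factor Sox9 rose by 1.05, SE 0.17, and Gc of the liver list by 2.33, SE 0.22, a list whose adjusted p was 0.0616. No other list passed camera with DN-REST.

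Infection with both viruses, compared with the mCherry group, asks for the joint effect. Pyy reached 2854 ± 473 CPM (log2 fold change 6.03, SE 0.22, adjusted p = 3.35e-19, edgeR with BH adjustment; n = 4). Chga reached 543 ± 11.6 CPM (log2 fold change 6.14, SE 0.31, adjusted p = 5.42e-16), with Vgf at 372 ± 52.0 CPM (6.01, SE 0.21). Neurod1, a transcription factor of endocrine and neuronal cells (chromosome 2, 79452521 to 79456751, minus strand), counted 1, 0, 0, 0 UMIs in mCherry libraries A to D and 25, 16, 30, 32 in those of the combination, a CPM ratio of 80.7 (14.2 to 3219.6; adjusted p = 2.49e-06). Pcsk1, a protease that processes prohormones, had a ratio of 71.7 (19.6 to 597; adjusted p = 7.07e-09), and Iapp one of 20.4 (5.37 to 173). Cpa1 stood at 1271 ± 202 CPM (4.30, SE 0.17) and Reg2 was higher by 5.91, SE 0.21. The interferon response list had 13 members that rose and 1 that fell, of 21 tested. Irf7, a transcription factor of the interferon response (chromosome 7, 141262706 to 141266481, minus strand), went from 5.39 ± 2.94 to 49.2 ± 10.0 CPM (log2 fold change 3.12, SE 0.27, adjusted p = 9.23e-11). The neutrophil chemokine Cxcl5 fell (-2.09, SE 0.15).

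In the combination 3375 genes passed the test (33.0%), 1767 higher and 1608 lower. With scaling by total UMIs the split was 1478 higher and 2081 lower, or 41.5% higher in place of 52.4%. Under total-UMI scaling the median log2 fold change over all genes was -0.120 in this comparison, against -0.029 with TMM scaling, and -0.092 to -0.020 in the others. Kirrel3, a cell adhesion protein, had a CPM ratio of 551 (98.6 to 21796), Aqp5, a water channel, 186 (51.1 to 1538), and Gsx1, a homeobox factor of the developing brain, 119 (40.4 to 579). Gng4 and Slc17a6, a glutamate transporter of neurons, had no control UMI and were at least 27.96-fold and at least 25.3-fold higher. Tnfrsf26 fell by a ratio of 75.3 (20.4 to 629) and Dsg3, a desmosome protein, by 25.5 (6.62 to 218).

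All 27 members of the acinar enzyme list rose in the combination, the same adjusted over the list alone (median 4.22, camera adjusted p = 1.65e-33, and 0.00339 with an estimated correlation). Among RE1 targets 26 rose and 2 fell of 34, with 28 and 2 adjusted over the list alone (median 3.46, adjusted p = 1.64e-15). Among neuroendocrine granule genes 12 rose and 1 fell of 19, with 13 and 1 adjusted over the list alone (median 3.40, adjusted p = 5.20e-08). Of 7 hormone genes 6 rose, the same adjusted over the list alone (adjusted p = 5.70e-05). Ins1, Ins2, Sst and the transcription factors Neurog3, Mafa, Pax6 and Isl1 were not among the genes with UMI counts and were not analysed here. The hormone list was written with 19 genes, the beta-cell list with 27 and the endocrine transcription factor list with 26. Most members of these lists could not be tested, so their counts cover only a part of each list. Endocrine transcription factors went both ways: 1 rose and 4 fell of 9, the same adjusted over the list alone (adjusted p = 0.469). Beta-cell genes, of which 3 of 7 rose (the same adjusted over the list alone), had an adjusted p of 0.0159, and 0.0766 with an estimated correlation. Of these rises, Iapp and Pcsk1 are shared with the hormone and granule lists. Interferon response genes rose (13 rose and 1 fell of 21, the same adjusted over the list alone; median 0.85, adjusted p = 2.22e-04). They included Bst2 (1.58, SE 0.15), which tethers virus particles, and H2-D1 of antigen presentation (0.85, SE 0.09).

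Inflammatory chemokines were lower in the combination (1 rose and 6 fell of 19, with 1 and 7 adjusted over the list alone; adjusted p = 0.0182, and 0.0835 with an estimated correlation). Injury and Reg genes (9 rose and 3 fell of 19, with 10 and 4 adjusted over the list alone) had an adjusted p of 0.00957, and 0.0752 with an estimated correlation. Stomach and intestine genes (5 rose and 1 fell of 8, the same adjusted over the list alone) had one of 0.0108, and 0.220 with an estimated correlation. For p53 genes (2 rose and 8 fell of 19, the same adjusted over the list alone) it was 0.0149, and 0.142 with an estimated correlation. Of 29 cell cycle genes 2 rose and 8 fell, the same adjusted over the list alone, without passing as a set (median -0.25, adjusted p = 0.130). Mcm4, a subunit of the replicative helicase, rose by 1.76, SE 0.11. Fibroblast markers did not pass either (4 rose and 3 fell of 18, with 6 and 3 adjusted over the list alone; adjusted p = 0.598). Their median of 0.44 and the direction of fry differed in sign. Ly6c1 of the endothelial list rose by 2.99, SE 0.15, a list with an adjusted p of 0.136.

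**Figure D3:**
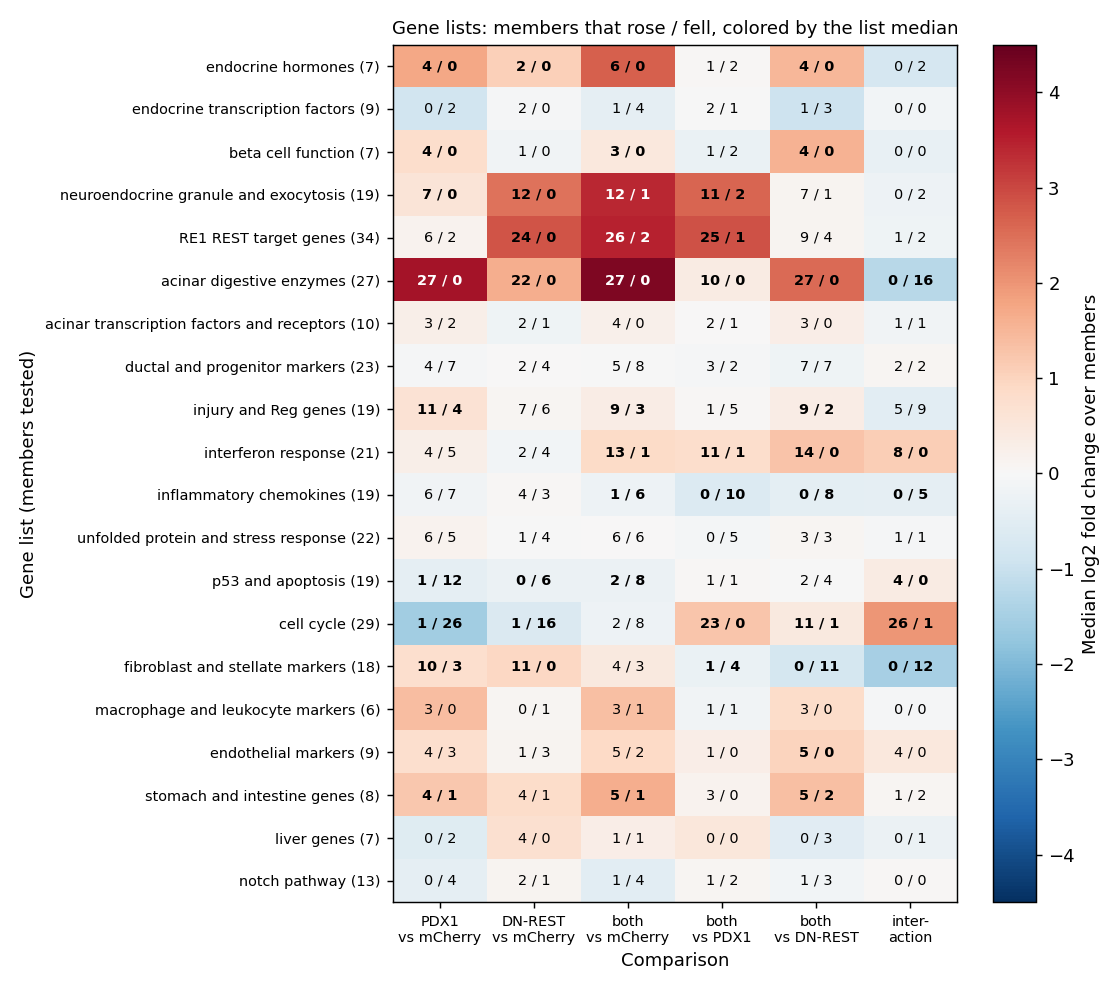
Gene lists (vertical, with the number of members tested) against the 6 comparisons (horizontal). Color is the median log2 fold change over the members and each cell gives how many members rose / fell in the edgeR test, in bold where camera's adjusted p was under 0.05. RE1 targets and neuroendocrine genes rose where DN-REST was added (medians 2.84 and 2.45), the acinar enzyme list rose with each virus (medians 3.76 and 1.63), and cell cycle genes fell with each single virus (medians -1.57 and -0.64).

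Set against PDX1 alone, the combination shows what changes when DN-REST is added to PDX1, with Pdx1 itself also higher and a total titer that may be higher. Chga went from 21.3 ± 18.7 to 543 ± 11.6 CPM (log2 fold change 4.69, SE 0.27, adjusted p = 6.99e-14, edgeR with BH adjustment; n = 4). Vgf went from 11.3 ± 4.46 to 372 ± 52.0 (5.03, SE 0.19), and Neurod1 rose by 3.83, SE 0.64. Cdk5r2, an activator of a neuronal kinase, rose by 5.51, SE 0.24, and Npas1, a neuronal transcription factor, by a CPM ratio of 115 (20.3 to 4583). Irf7 went from 10.5 ± 2.93 to 49.2 ± 10.0 CPM (2.24, SE 0.24) and Ube2c from 47.6 ± 7.89 to 213 ± 29.2 (2.17, SE 0.14). Iapp fell from 12.1 ± 0.999 to 4.11 ± 1.98 CPM (-1.58, SE 0.41), the acute phase gene Saa3 fell (-2.22, SE 0.21), and Serpinb12 went from 118 ± 14.7 to 4.498 ± 2.90 CPM (-4.73, SE 0.29).

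Between those groups 1553 genes passed the test, 893 higher and 660 lower in the combination. Total-UMI scaling gave 701 and 951, or 42.4% higher in place of 57.5%. RE1 targets rose as a set (25 rose and 1 fell of 34, with 26 and 1 adjusted over the list alone; median 2.87, camera adjusted p = 3.42e-25). Neuroendocrine granule genes did so too (11 rose and 2 fell of 19, the same adjusted over the list alone; median 2.60, adjusted p = 3.81e-07). Cell cycle genes rose over PDX1 alone (23 of 29, 25 adjusted over the list alone; median 1.25, adjusted p = 8.66e-20, and 0.00337 with an estimated correlation), and so did interferon response genes (11 rose and 1 fell of 21, with 12 and 1 adjusted over the list alone; median 0.80, adjusted p = 9.70e-08). Of 19 chemokine genes 10 fell, 11 adjusted over the list alone (median -0.62, adjusted p = 1.65e-05). The acinar enzyme list was raised further in 10 of 27 members, 12 adjusted over the list alone (median 0.37, adjusted p = 8.70e-04, and 0.332 with an estimated correlation). Fibroblast markers (1 rose and 4 fell of 18, the same adjusted over the list alone) had an adjusted p of 0.0154, and 0.398 with an estimated correlation. Hormone genes (adjusted p = 0.955) and endocrine transcription factors (0.569) did not pass.

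Set against DN-REST alone, the combination shows what changes when PDX1 is added to the block of REST, with a total titer that may be higher. Pyy went from 90.9 ± 37.8 to 2854 ± 473 CPM (log2 fold change 4.97, SE 0.21, adjusted p = 6.80e-18, edgeR with BH adjustment; n = 4). Cckar rose by 4.40, SE 0.16 and Reg2 by 3.87, SE 0.17. Some genes that rose with DN-REST alone were higher again, Chga by 2.72, SE 0.23, Disp2 by 1.62, SE 0.28, Cdk5r2 by 1.14, SE 0.17 and Vgf by 0.86, SE 0.14. Prkcb, a protein kinase C, had a CPM ratio of 126 (22.1 to 5004) and Slc6a12, a betaine transporter, of 69.0 (23.3 to 337). Fn1 (-2.33, SE 0.11) and the chemokine Ccl20 (-2.98, SE 0.22) fell. So did Lce1h, a protein of the cornified envelope of skin with close relatives that can share reads (-4.87, SE 0.17).

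In this comparison 2370 genes passed the test, 1287 higher and 1083 lower. With total-UMI scaling these were 1104 and 1328, or 45.4% higher in place of 54.3%. RE1 targets did not pass camera (9 rose and 4 fell of 34, the same adjusted over the list alone; median 0.11, adjusted p = 0.557), nor did neuroendocrine granule genes (7 rose and 1 fell of 19, with 8 and 1 adjusted over the list alone; median 0.12, adjusted p = 0.130). All 27 members of the acinar enzyme list rose, the same adjusted over the list alone (median 2.55, camera adjusted p = 3.15e-30, and 0.00492 with an estimated correlation). Higher as sets were hormone genes (4 of 7 rose, 5 adjusted over the list alone; adjusted p = 0.00150) and beta-cell genes, which share Iapp with them (4 of 7, 5 adjusted over the list alone; 9.73e-04). The same held for interferon genes (14 of 21, the same adjusted over the list alone; 9.05e-08), endothelial markers (5 of 9, 6 adjusted over the list alone; 0.00132) and injury and Reg genes (9 rose and 2 fell of 19, with 11 and 3 adjusted over the list alone; 0.00120). Chemokines fell in 8 of 19 members, 10 adjusted over the list alone (adjusted p = 3.10e-04). A call that ended with an estimated correlation was that of cell cycle genes (11 rose and 1 fell of 29, with 12 and 1 adjusted over the list alone; adjusted p = 0.0155, and 0.332 with an estimated correlation). Others were those of stomach genes (5 rose and 2 fell of 8, the same adjusted over the list alone; 0.0159, and p = 0.246 with an estimated correlation) and fibroblast markers (11 of 18 fell; adjusted over the list alone 1 rose and 12 fell; 2.99e-05, and p = 0.148 with an estimated correlation).

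The interaction asks whether the combined effect differs from the sum of the single effects on the log2 scale. Most genes of the cell cycle list had a positive interaction. Ube2c (chromosome 2, 164769898 to 164778822, plus strand) averaged 157, 47.6, 107 and 213 CPM in the mCherry, PDX1, DN-REST and combination groups, an interaction of 2.72 (SE 0.20, adjusted p = 7.75e-11, edgeR with BH adjustment). The interaction was 3.20, SE 0.35, for the mitotic cyclin Ccnb2 and 3.01, SE 0.32, for Plk1. For digestive enzymes the combination fell short of the sum of the single effects, as in Cpa1 (-2.01, SE 0.21) and Prss2 (-1.59, SE 0.16). Reg3g had an interaction of -4.71, SE 0.28, and the fibroblast genes Vim and Tagln of -2.33, SE 0.18, and -1.77, SE 0.22. The antiviral genes Oasl1 (2.55, SE 0.36) and Usp18 (2.59, SE 0.52) were higher than the single effects add up to, and the chemokine Ccl2 lower (-2.18, SE 0.25). For Chga the interaction of 1.27 (SE 0.44) did not pass (adjusted p = 0.0750).

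An interaction passed the test in 841 genes (8.22%), 478 positive and 363 negative. Total-UMI scaling gave 428 and 440, or 49.3% positive in place of 56.8%. As sets, cell cycle genes (26 of 29 positive and 1 negative, with 27 and 1 adjusted over the list alone; median 1.99, camera adjusted p = 1.25e-27) and interferon genes (8 of 21 positive; adjusted over the list alone 13 positive and 1 negative; median 1.11, 2.77e-07) had a positive interaction. The acinar enzyme list (16 of 27 negative, 22 adjusted over the list alone; median -1.23, 6.03e-15) had a negative one. So had fibroblast markers (12 of 18 negative; adjusted over the list alone 1 positive and 14 negative; 4.41e-10) and chemokines (5 of 19 negative; adjusted over the list alone 1 positive and 6 negative; 7.74e-04). The positive interaction of p53 genes (4 of 19, 7 adjusted over the list alone; adjusted p = 0.00905) had a p of 0.116 with an estimated correlation. Hormone genes did not pass (2 of 7 negative, 3 adjusted over the list alone; median -0.77, adjusted p = 0.0537), nor did RE1 targets (median -0.20, adjusted p = 0.755). The stated titers sum to 40 infectious units per nl in the mCherry and combination groups. If cells given a single virus received no control virus, the sum was 10 in the PDX1 group and 30 in the DN-REST group, and an effect of total titer would enter the interaction.

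**Figure D4:**
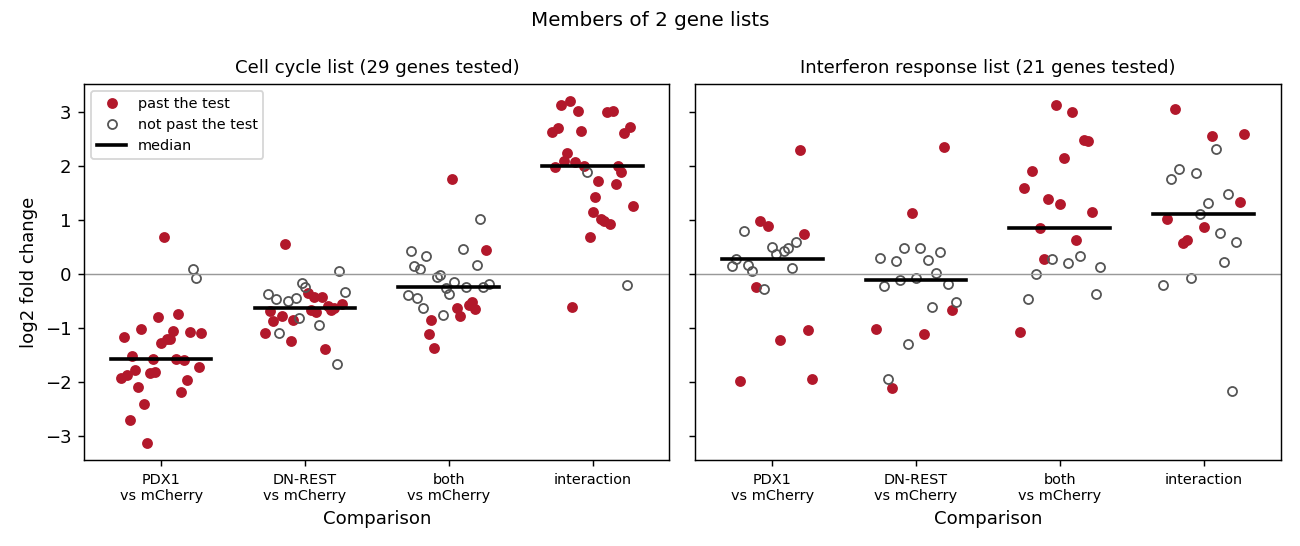
log2 fold change (vertical) of the tested members of the cell cycle list (left, 29 genes) and the interferon response list (right, 21 genes) with PDX1, DN-REST and both viruses against mCherry, and their interaction. Each dot is a gene, filled where it passed the edgeR test, and the line is the median, which for cell cycle genes was -1.57, -0.64, -0.25 and 1.99.

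A gene was counted as beyond both single viruses where the combination differed from each of them in the same direction. This held for 522 genes, 334 higher and 188 lower. With total-UMI scaling the split was 256 and 313, or 45.0% higher in place of 64.0%. Chga, Vgf, Cdk5r2, Irf7 and Mcm4 were among the higher ones, Mcm4 by 2.11, SE 0.11, over DN-REST alone.

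The lists of genes moved by PDX1 and by DN-REST were also compared. They shared 662 genes with the same direction, 309 higher and 353 lower, and 115 had opposite directions. Both comparisons use the same control libraries. In 20 simulations of unchanged groups edgeR called 0.15 and 0.3 genes on average, too few to share any, so the simulations set no chance level for this count. Independent lists of these sizes would share 112 higher and 90.7 lower. With the controls split so that each virus had its own pair, 323 to 374 genes were shared and the covariance was 0.177 to 0.216. Across the 10225 genes, which are not independent replicates, the correlation of the log2 fold changes was 0.380 against a mean of 0.536 in the simulations, and the covariance 0.221 against 0.0520, a difference of 0.169.

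The authors' deposited table lists genes of 6 comparisons with their own fold changes. At their adjusted p of at most 0.05 and at least 2-fold, the authors' deposited table holds 1231 genes for PDX1, 476 for DN-REST and 1373 for the combination against mCherry. Of those also tested here, 96.0%, 96.8% and 96.8% of the genes of the authors' deposited table passed the edgeR test in the same direction, and none in the opposite direction.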

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

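The splits of the libraries and the tests of library depth were written before their results were seen. The tests of titer, of acinar cells of a single profile, of fibroblasts and of leukocytes were chosen after the result was seen. Thinning to equal depth was added as an alternative after seeing the data.

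Members of the acinar enzyme list were higher than with mCherry in each of the other groups, with list medians of 3.76 (PDX1), 1.63 (DN-REST) and 4.22 (combination) and a negative interaction of -1.23. The stated titers sum to the same value in the mCherry and combination groups, whose list median differed by 4.22 (SD over members 0.919). For that difference this argues against titer. If cells given a single virus received no control virus, an effect of titer could still enter the PDX1 and DN-REST comparisons and the interaction. More acinar cells of an unchanging profile would multiply every member's gain by the same factor, but the gain with DN-REST over that with PDX1 varied between members with a chi-square per degree of freedom of 10.4. Thinning to equal depth kept the medians at 0.966 of their size or more. As thinning leaves the expected share of UMIs of each gene unchanged, this test could not decide on depth. A hypothesis that stays open is that PDX1 and the block of REST each change the transcript levels of acinar genes. It arose from the same data on which the other explanations were tested, and was not itself tested. Cell survival was not measured.

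Cell cycle genes were lower with each single virus (medians -1.57 and -0.64), while the combination had a median of -0.25 and the interaction 1.99. A change in the number of fibroblasts would move fibroblast markers the same way, and their median interaction was -1.49 (SE over members, which are not independent replicates, 0.289). A change in the share of fibroblasts that divide need not move these markers and was not tested. Thinning left the median at 0.997 of its size, which for the same reason cannot decide on depth. Titer stays open: if cells given a single virus received no control virus, which the labels do not say, the summed titers were 40, 10, 30 and 40, and an effect of titer that raised these genes would enter the interaction of 1.99. An interplay of PDX1 and REST in cell division therefore remains an untested alternative.

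Interferon response genes were higher in the combination than in each other group, with a median interaction of 1.11. The combination and mCherry groups, whose stated titers have equal sums, differed by a median of 0.853 (SE over members, which are not independent replicates, 0.257). For that difference this argues against titer. If cells given a single virus received no control virus, an effect of titer could still enter the comparisons with those groups and the interaction. Thinning left the medians at 0.976 of their size or more, which again cannot decide on depth. Leukocytes in the cultures may contribute: their 6 tested markers had a median of -0.143 in the combination over PDX1, but with an SD of 0.905 and 1 marker under 10 UMIs, a minimum set after that median was seen, the test leaves this open. The labels name no sort that would remove such cells, the list did not pass camera in any comparison, and its most abundant members went from 85.4 to 47.9 CPM (Cd14) and from 35.3 to 69.1 CPM (Cd68) between the PDX1 and combination groups.

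Effects of DN-REST with and without PDX1 differed, by camera on the interaction, in 6 lists: the 3 above, chemokines (median -0.39), p53 and apoptosis genes (0.38, adjusted p = 0.116 with an estimated correlation) and fibroblast markers (-1.49). Among single genes (edgeR with BH adjustment) the interaction was 5.83 for C1ql1 (adjusted p = 4.94e-04), 5.08 for Sp9 (0.00128) and 4.33 for Il33 (5.72e-06). It was -5.96 for Plbd1 (5.45e-04), an uncertain size, as Plbd1 had 1 UMI in the mCherry group. For Serpinb12 it was -5.46 (8.34e-08) and for Tnfrsf18 -4.97 (1.39e-06). Mir692-1 had 5.47 (0.00127), which rests on combination libraries C and D with 4699 and 8363 UMIs against 79 and 91 in A and B. For Crabp1 the interaction was 4.11 (0.0127) and 2.75 (0.258) after thinning. For Myl1 it was -8.20 (0.00363), -5.86 (0.170) after thinning and -6.70 (0.167) without DN-REST library D, and since Myl1 had no control UMI the fitted size is no bound. For Sprr1b it was -5.41 (0.0104), and -3.41 (0.0982) without PDX1 library B.

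A library stood apart from the other 3 of its group in 21 of 189 groups of values checked, where chance gives about 1 in 20. The measure is the gap to the nearest library over the whole range. For the share of ribosomal protein genes this ratio was 0.847, with 13.1% against 13.5% in each of the others, in mCherry library D. In PDX1 library A it was 0.886, with 12.04% against 11.7% in each of the others. For the share of fibroblast markers it was 0.858, with 0.853% against 0.730 to 0.747%, in DN-REST library D. In combination library D it was 0.895, with 0.275% against 0.225 to 0.230%. In CPM of the PDX1 group it was 0.854, with 2887 against 2388 to 2461, for Pyy in library C. It was 0.896, with 14.99 against 2.76 to 4.04, for Xirp2 in D and 0.952, with 12.1 against 0.666 to 1.21, for Sprr1b in B. In the DN-REST group it was 0.867, with 9.01 against 12.6 to 13.1, for Stmn3 in B. It was 0.877, with 13.3 against 4.12 to 5.25, for Sarm1 in B and 0.893, with 9.21 against 2.92 to 3.59, for Pdx1 in D. In the mCherry group it was 0.843, with 15.4 against 7.20 to 8.49, for Crabp1 in D and 0.897, with 15.1 against 18.9 to 19.3, for Sox9 in D.

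The combination group had the remaining ones. Library A stood apart for Trim12c (0.991, with 511 against 4.32 to 8.68), Asphd1 (0.955, with 22.7 against 14.996 to 15.3), Sarm1 (0.860, with 1.46 against 5.28 to 5.91) and C1ql1 (0.903, with 6.41 against 4.09 to 4.32). Library C did so for Xirp2 (0.916, with 7.84 against 1.51 to 2.04) and Ap3b2 (0.922, with 31.0 against 54.8 to 56.8). Library D stood apart for Gng4 (0.899, with 5.45 against 9.03 to 9.44), Slc17a6 (0.949, with 11.6 against 4.91 to 5.25) and Avp (0.903, with 28.9 against 21.1 to 21.9). Trim12c passed the test over DN-REST with a log2 fold change of 6.51 (SE 1.17, adjusted p = 8.05e-05), which fell to 2.02 (adjusted p = 0.0332) without combination library A.

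Chance assignment of libraries to groups was excluded at a share of 0.05 for each count of a pair of groups, but not for the other counts. The real groups called 3152 (PDX1), 1315 (DN-REST), 3375 (combination), 1553 (combination over PDX1) and 2370 genes (over DN-REST). In each of these 1 of the 35 splits of the same 8 libraries, the real one, gave as many, and the highest of the other splits was 0, 0, 0, 1 and 1. For the genes beyond both single viruses 1 of 100 splits gave as many as the real 522, the highest other being 0. Those splits mix libraries of the PDX1, DN-REST and combination groups, which differ from each other. Mixing widens the spread within each drawn group, so they cannot decide whether chance gives the count of 522. For the interaction 4 of 100 splits gave at least as many as the real 841, the highest other being 1266. The 3 others each placed 1 of the 8 libraries with PDX1 on the plus side and so nearly parted libraries with PDX1 from those without, a structure of the samples. These splits mix libraries of all 4 groups, so effects of the single viruses can enter the interaction. They therefore cannot decide whether chance gives the count of 841.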

How the results depend on the processing

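The alternatives were fixed before the data were examined, except the thinning of all libraries to the smallest total, which was chosen after seeing the data. Each count of genes past the test, both directions together, stayed within 1.5 times its value under every alternative run. By direction, the genes lower beyond both single viruses went from 188 to 313 with total-UMI scaling. Apart from leaving out a library, the counts ran from 2736 to 3315 for PDX1, 1077 to 1454 for DN-REST, 3012 to 3559 for the combination, 1228 to 1729 for the combination over PDX1, 1928 to 2532 over DN-REST, 643 to 984 for the interaction and 389 to 610 beyond both single viruses. With 1 library left out in turn they were 2713 to 2888, 989 to 1171, 2995 to 3139, 1218 to 1465, 2002 to 2110, 716 to 815 and 406 to 510. The fit of the compared groups alone cannot give the interaction and was not run for it. The overlap of the single-virus lists was 711 with DESeq2 and 504 to 650 with a library left out; the 6 uses of split controls gave 367, 374, 342, 325, 325 and 323 in place of 662, with fewer controls in each comparison by construction.

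The replicate letters did not meet the rule for pairing, which asks for a correlation above 0.1 in every pair: deviations from the group means of same-lettered libraries correlated at 0.0907 on average (-0.0960 to 0.267; 10 of 24 pairs above 0.1), against -0.0303 for different letters. Of 48 best matches 32 were of the same letter, where chance gives 12, a hint from the data of some shared structure. With the letter as a replicate block the counts in the order above were 3315, 1454, 3516, 1729, 2532, 984 and 610. In camera the block brought the interaction of hormone genes from an adjusted p of 0.0537 to 0.0462 and changed no other list call.

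Of 482 calls of named genes 412 passed in every setting run, those given in the report as risen or fallen between groups among them except Pdx1 in the combination over PDX1, and none reversed. The 17 results of named genes that reversed were not past the test. Thinning turned the interaction of Hes6 to 0.048, Pdx1 to 0.056, Ppy to 0.15, Nkx6-1 to 0.0046 and Stmn2 to -0.12, and with PDX1 Gcg to 0.03 and Stmn2 to 0.24; the cause was not tested. Leaving out a library gave log2 ranges that cross 0. For the interaction these were -0.0069 to 0.33 for Cd14, -0.13 to 0.083 for Hes6, -0.47 to 0.33 for Pdx1, -1.74 to 0.14 for Ppy, -1.52 to 1.37 for Neurod1, -0.47 to 0.58 for Nkx6-1, -0.20 to 0.65 for Stmn2 and -0.0057 to 0.18 for Krt19. With PDX1 they were -0.95 to 0.072 for Gcg, -0.41 to 0.51 for Snap25 and -0.55 to 0.29 for Stmn2, and with DN-REST -0.060 to 0.72 for Gcg and -0.35 to 0.17 for Nkx6-1. For the combination over PDX1 they were -0.70 to 0.14 for Gcg, -0.56 to 0.49 for Nkx6-1 and -0.15 to 0.029 for Krt19, and over DN-REST -0.11 to 0.21 for Stmn2; the cause was not tested.

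Of 120 list results, 18 calls ended with an estimated correlation, each given in the report. Fry, which does not compare a list with other genes, passed 30 list results that camera had not called, 3.21e-04 for granule genes in the combination over DN-REST being one, and ended the call of fibroblast markers with PDX1 (0.0651). Fry turned the direction of 6 lists that camera had not called, at signed adjusted p-values of 0.703 (acinar regulators, DN-REST), -0.879 (leukocytes, DN-REST), 0.989 (Notch, DN-REST), -0.879 (fibroblasts, combination), 0.924 (beta cell, combination over PDX1) and -0.989 (endocrine factors, interaction), where the sign is the direction; the cause was not tested. At this depth, number of libraries and spread the test found part of the simulated changes: of 100 genes simulated with a 2-fold change, 65 were found for PDX1, 62 for DN-REST, 70 for the combination and 43 for the interaction, and of 100 with a 4-fold change 95, 90, 97 and 78. Fewer genes were changed in the simulations than passed in the data. The BH adjustment depends on that share, so these rates need not hold for the real comparisons.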

Other observations

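Genes of the cornified envelope, the protein shell of skin cells, lie in the Sprr and Lce families and were chosen after their values were seen. All 4 tested Lce genes rose with DN-REST, and 3 fell with PDX1 (edgeR with BH adjustment). Lce1h averaged 308 CPM with mCherry, 27.6 with PDX1, 1097 with DN-REST and 37.6 with both (log2 fold change -3.50, SE 0.17, adjusted p = 2.20e-16 for PDX1 and 1.83, SE 0.14, adjusted p = 4.77e-11 for DN-REST). Lce1g and Sprr1a had the same directions, with -2.15 and -1.97 for PDX1 and 2.03 and 1.499 for DN-REST. The 10 tested Sprr genes went both ways, with 6 risen and 3 fallen with PDX1 and 3 risen and 5 fallen with DN-REST; the rise of Sprr1b with PDX1 was not past the test without PDX1 library B. Directions opposite to those of Sprr1a were found for Sprr2b (3.79 with PDX1 and -1.58 with DN-REST), Sprr2d (4.52 and -1.99) and Sprr2f (2.71 and -1.87). Sprr2g (-2.62 and -3.13) and Sprr2h (-2.26 and -1.42) fell with each. Each call given with its value held in all 16 alternatives run for it, leaving out single libraries and thinning, which was added after seeing the data, included. Near-identical members can share reads, so a direction belongs to a group of relatives rather than with certainty to a single gene. No explanation was tested.

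Of the 478 genes with a positive interaction, 109 were higher in the combination than with mCherry, 155 were lower and 214 did not pass that test. Of the 363 with a negative interaction, 144 were higher, 61 lower and 158 did not pass.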
